A study of Leucoraja erinaceus with 4 samples.

How the data were processed

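Total RNA of the synarcual and post-synarcual regions was sequenced after the central nervous system and axial muscle had been dissected away, per the labels' protocols. The libraries were made with an unstranded TruSeq kit and sequenced as 100 bp pairs in 1 shared lane of a HiSeq2000. The labels give 132470224 reads for the lane, a mean read length of 93 bp and a minimum RNA integrity number of 8.0. The protocol mentions males at each stage and does not say how many animals went into each library. It is read here as the same males giving both regions of a stage.

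The authors' files hold estimated counts (RSEM's expected count), TPM and FPKM per assembled gene for each library, per the file headers. Bowtie2 and RSEM are named in the submitters' processing notes, and their versions and any filter on features are not given in the sources used here. The feature identifiers carry the prefix TRINITY, the name of a de novo assembler. The authors' estimated counts are not normalized, the deposited TPM values are corrected for length and scaled to the same total in each library, and the deposited FPKM values were not used in any comparison. A deposited table of the whole series holds the same estimated counts: the largest difference from the per-sample files was 0. Lengths per feature are those the authors' files give. Of the features, 86.4% have 1 transcript, and 2658 share an assembly component with another feature, so that reads of 1 gene or of close copies may be split between features. Because the kit is unstranded, reads from overlapping transcripts on opposite strands cannot be told apart. Counts of such features are uncertain, among them TRINITY_DN44861_c3_g2 and TRINITY_DN35449_c1_g1, whose components hold 2 features each.

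Estimated counts were rounded to whole numbers; between 1.66% and 1.89% of values per library were not whole as deposited. Totals ranged from 3922525 to 5092346. Whether a count stands for a read or a read pair is not given in the sources used here, and if it is a read, the intervals and floors are too narrow. A count of 0 allows up to 3 counts, which is 0.521 CPM in the stage 28 synarcual, 0.533 in the stage 28 post-synarcual, 0.769 in the stage 33 synarcual and 0.986 in the stage 33 post-synarcual. Sequencing without molecular identifiers does not count independent molecules, so intervals and floors cover counting error only. TMM factors from edgeR 4.0.16 (R 4.3.3) on the 14668 features with at least 10 counts in at least 2 libraries were 1.39 and 1.44 for the stage 28 synarcual and post-synarcual and 0.831 and 0.599 at stage 33. Log2 CPM used a prior count of 2. With this scaling the median fold of all features lay within 0.1 log2 of 0 in every comparison.

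Comparisons were fixed before the data were examined. Within a stage or a region, where each group has 1 library, a feature counted as different when its log2 fold was at least 1 in size and its higher count at least 50, with no p-value. Printed folds are ratios of scaled counts with exact 95% Clopper-Pearson intervals. For region over both stages, edgeR's quasi-likelihood test was fitted to all 4 libraries with stage as a block, and p-values were adjusted by the Benjamini-Hochberg method. That fit has 1 residual degree of freedom, the interaction of stage and region, and its common dispersion was 0.0409, which is a coefficient of variation of 20.2%. Its p-values rest on the spread of the region difference between 2 stages, not between animals of a stage. That spread was pooled over features, with 5.33 prior degrees of freedom against 1 residual. Stage was not tested.

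Features were named by a rule fixed beforehand for files without gene names: the 2 identifiers in each direction with the largest mean fold among those at least 2-fold apart the same way in both stages (region) or both regions (stage), and the 2 in each direction with the largest region fold at 1 stage whose fold at the other was under 0.5 log2 or of opposite sign, so that the latter can include features different at both stages in opposite directions and features with too few counts at the other stage to measure a fold. The lists of genes planned for the tissue were not applied. The late-high and early-high classes were added after the data were examined. Their mean stage fold and the mean region fold are orthogonal contrasts of the 4 libraries, so libraries of equal error do not correlate them. Unequal error can correlate them, and effective library sizes ran from 3042144 to 5753483. At these sizes, simulated counting error alone gave correlations across features from -0.0325 to -0.00012. A spread beyond counting error that differs between libraries was not simulated.

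The test was checked on simulated data with 14668 features, 50 changed by each of 4 folds. Each change had the same fold at both stages, so region folds that differ between stages are not covered. With 1 spread for all features, edgeR's region test recovered 22, 49, 50 and 49 of 50 at 2-, 4-, 8- and 16-fold, with 11 unchanged features called. With a spread drawn per feature it recovered 8, 46, 50 and 49, with 32 unchanged features called. The rule of size at both stages recovered 15, 41, 46 and 47 in the first case, with 2 unchanged features called, and 11, 41, 46 and 48 in the second, with 47. Both spreads were taken from the fit to these 4 libraries, so the recoveries need not hold for the data. There TRINITY_DN35904_c1_g1, singled out after its values were seen, had log2 region folds of -2.88 at stage 28 and -2.21 at stage 33. Its adjusted p by edgeR's region test was 0.0953. Alternatives were DESeq2 1.42.0 size factors and its Wald test, total-count scaling, other prior counts, count minimums, folds and low-count filters, TPM with a pseudocount of 1, the fit without the stage block, and counts summed over the features of an assembly component.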

Results

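RNA was sequenced from the cartilaginous axial skeleton of embryos of the little skate, Leucoraja erinaceus (also written erinacea), a cartilaginous fish. The synarcual is the fused block of cartilage at the front of the skate's vertebral column, and the post-synarcual is the axial skeleton behind it, where the vertebrae remain separate. Both regions were dissected from males at stage 28 and at stage 33, and each combination of stage and region gave 1 library, so the data set holds 4 libraries in 4 groups of 1. The series title gives the development of the synarcual as its subject, and the design compares the 2 regions and the 2 stages. Expression was quantified over 23105 assembled features, which are the genes of a de novo transcriptome with a median length of 1252 bp. The files pair none of these features with a gene name, and 0 of the identifiers matched the RefSeq table of the species, so features are reported by their assembly identifiers. No chromosome position or functional class is given for any of them, and the lists of skeletal, patterning and cell type genes fixed before the data were examined were not used here. The total count was 4167062 in the stage 28 synarcual, 3922525 in the stage 28 post-synarcual, 4713268 in the stage 33 synarcual and 5092346 in the stage 33 post-synarcual. With 1 library per group, a difference between 2 libraries has no replicate check, and the intervals below cover counting error only.

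The 4 libraries differed first by stage in how their counts were spread over features. At stage 28 the 10 most abundant features held 8.58% of counts in the synarcual and 8.22% in the post-synarcual. At stage 33 they held 24.5% and 29.7%. The number of features that together held 50% of a library's counts was 748 and 837 at stage 28, against 136 in the synarcual and 39 in the post-synarcual at stage 33. The most abundant feature of both stage 33 libraries was TRINITY_DN37437_c0_g1, a feature of 6020 bp singled out after its values were seen. It took 7.79% of the stage 33 synarcual counts (95% Clopper-Pearson interval 7.77 to 7.82) and 6.88% of the post-synarcual counts (6.86 to 6.90), against 0.131% and 0.339% at stage 28. Of the 10 most abundant features per library, 9 were shared between the stage 28 regions, 7 between the stage 33 regions and 3 among all 4 libraries.

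**Figure D1:**
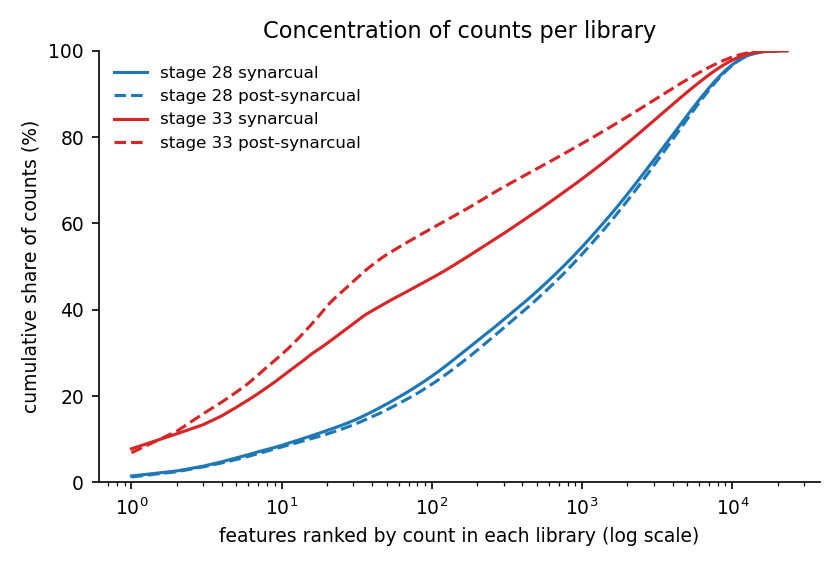
Cumulative share of each library's counts (y axis, percent) against features ranked by their count in that library (x axis, log scale), with stage 28 in blue, stage 33 in red, the synarcual as solid and the post-synarcual as dashed lines. The stage 33 lines lie above the stage 28 lines, and the 10 most abundant features reach 29.7% in the stage 33 post-synarcual against 8.22% in the stage 28 post-synarcual.

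Across the 14668 features with at least 10 counts in at least 2 libraries, expression profiles were closest between the regions of one stage. The correlation across features of log2 CPM, a count scaled by library size, was 0.94 between the regions at stage 28 and 0.95 at stage 33. Between stages it was 0.70 in the synarcual and 0.74 in the post-synarcual, and features are not independent replicates. When the 4 values of each feature were split into a stage, a region and an interaction contrast, stage accounted for 82.0% of their summed variance, region for 11.9% and the interaction for 6.11%. Of 11340 features with at least 50 counts in some library, 3599 differed at least 2-fold by the stage contrast, 798 by the region contrast and 244 by the interaction contrast. The interaction contrast is the difference of the region folds of the 2 stages divided by 2 on the log2 scale, so those 244 had region folds at least 4-fold apart.

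The first comparison asked how the axial skeleton at stage 33 differed from that at stage 28. In the synarcual, 2012 features were at least 2-fold higher and 1751 at least 2-fold lower at stage 33, out of 10888 with at least 50 counts in the higher library. In the post-synarcual, 1662 were higher and 1637 lower out of 10515. With trimmed-mean (TMM) scaling, 308 features in the synarcual and 280 in the post-synarcual were at least 16-fold higher at stage 33, against 90 and 60 that were at least 16-fold lower. The features were largely shared between regions, with 1223 higher in both and 1044 lower in both, where independent lists would share 262 and 229. The stage folds of the 2 regions correlated across features (Pearson r = 0.86, Spearman rho = 0.80), and these folds have no library in common. Both regions of a stage are read as coming from the same males, so the stage folds share their animals, which the values for independent lists leave out.

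The largest stage difference shared by both regions was that of TRINITY_DN39530_c0_g4, a feature of 3025 bp. It had 57510 counts in the stage 33 synarcual and 101759 in the stage 33 post-synarcual, against 1 and 0 at stage 28. Its fold was 84849 in the synarcual (95% counting interval 15228 to 3351400). In the post-synarcual it was at least 51077-fold higher, the lower 95% bound against a count of 0. TRINITY_DN43754_c0_g1 (1752 bp) went from 1 to 5753 counts in the synarcual, a ratio of 8488 with an interval of 1523 to 335310. In the post-synarcual it went from 3 to 15896 counts, a ratio of 9811 with an interval of 3357 to 47580. In the other direction, TRINITY_DN25272_c0_g1 (1639 bp) had 370 counts in the stage 28 synarcual and 0 at stage 33. By the 95% bound it was at least 67.6-fold lower. Its post-synarcual counts were 271 and 3, a 48.8-fold lower level (16.5 to 238). TRINITY_DN34165_c0_g1 (1299 bp) went from 256 to 0 counts in the synarcual, at least 46.7-fold lower by the 95% bound. In the post-synarcual it went from 190 to 1, 103-fold lower (18.2 to 4074). No test was made of stage, because each stage is represented by 1 set of animals and stage and animal cannot be told apart. The split between higher and lower features rests on the scaling: 53.5% of the synarcual and 50.4% of the post-synarcual differences were upward with TMM scaling, against 20.1% and 9.50% when libraries were scaled to their total counts and 33.5% and 12.8% in TPM. Of the differences shared by both regions, 53.9% were upward with TMM scaling, 12.8% with total counts and 21.5% in TPM.

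**Figure D2:**
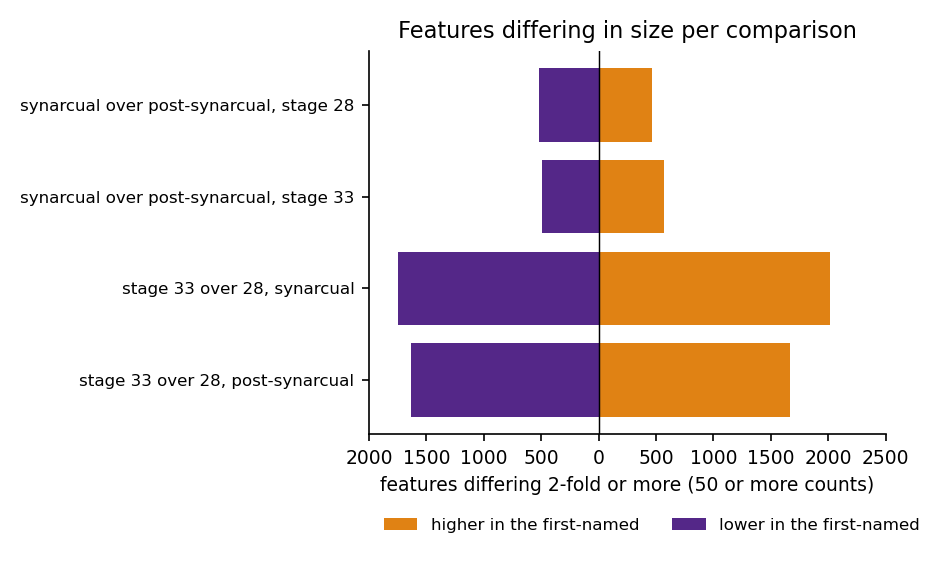
Number of features (x axis) that were at least 2-fold higher (orange, right of 0) or lower (purple, left of 0) in the first-named library of each comparison, among features with at least 50 counts in the higher library. The stage comparisons hold 3763 and 3299 such features and the region comparisons 987 and 1058.

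The second comparison asked how the synarcual differed from the post-synarcual. At stage 28, 465 features were at least 2-fold higher and 522 at least 2-fold lower in the synarcual, out of 10582 with at least 50 counts in the higher library. At stage 33 the numbers were 568 and 490 out of 9003. Differences of 4-fold or more were more frequent at stage 28, with 118 features higher and 173 lower in the synarcual, than at stage 33, with 2 higher and 31 lower. In 20 simulations without a region effect, counting error alone gave a mean of 1.35 features beyond 2-fold at stage 28 and 3.75 at stage 33. Counting error with the spread fitted below, as 1 value for all features, gave 315 and 316. These numbers were not simulated with a spread that varies between features. At stage 33 the upward share was 53.7%, against 85.8% when libraries were scaled to their total counts and 86.9% in TPM. Those scalings moved the median fold of all features there to 0.45 and 0.46 on the log2 scale.

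Among the 8206 features that could be compared at both stages, 111 were higher in the synarcual at both and 143 lower at both. Independent lists would share 11.9 and 14.4, and no library is common to the 2 stages. Of these shared differences 43.7% were upward, and 58.8% when libraries were scaled to their total counts. Independent lists leave out a spread that varies between features. In the test's check over 14668 features, such a spread gave 47 unchanged features called the same way at both stages, higher and lower together. The region folds of the 2 stages correlated weakly across the 14668 features (Pearson r = 0.32, Spearman rho = 0.26). In a joint model of the 4 libraries with stage as a block and 1 residual degree of freedom, no feature passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. The lowest adjusted p was 0.0953. Without adjustment, 1896 features had a p below 0.05, where 733 are expected by chance, and 998 of them were higher and 898 lower in the synarcual. At an adjusted p of 0.1, 14 features were higher and 59 lower. DESeq2's Wald test with the same model, its own size factors and its own filter on low counts called 222 features at 0.05, of which 46 were higher and 176 lower in the synarcual. Of those 222, 152 were also among the features at least 2-fold apart in the same direction at both stages. The Wald test and the rule of size use the same 4 libraries, so this overlap is not separate evidence.

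Among features different at both stages, those named here had the largest mean log2 fold in each direction with TMM scaling. The first were lower in the synarcual. TRINITY_DN44861_c3_g2 (353 bp) had 4 counts in the stage 28 synarcual and 116 in the post-synarcual, a 29.6-fold lower level (95% counting interval 11.3 to 111). At stage 33 it had 613 and 1486 counts and was 3.11-fold lower (2.83 to 3.42). TRINITY_DN41535_c0_g1 (6023 bp) had 126 and 2024 counts at stage 28, 16.4-fold lower in the synarcual (13.7 to 19.8). At stage 33 it had 93633 and 252871 counts, 3.46-fold lower (3.44 to 3.49). Of the features higher in the synarcual at both stages, TRINITY_DN23812_c0_g1 (593 bp) was 14.1-fold higher at stage 28 (6.91 to 33.4), with 115 against 8 counts, and 3.86-fold higher at stage 33 (2.71 to 5.62), with 188 against 38 counts. TRINITY_DN40644_c0_g1 (2247 bp) was 6.85-fold higher at stage 28 (4.66 to 10.4) and 2.54-fold higher at stage 33 (1.79 to 3.69). By edgeR's quasi-likelihood test their adjusted p values were 0.151, 0.296, 0.103 and 0.105 in the order given, so none of these 4 features passed.

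Other features met the rule of size at 1 stage without a fold of the same direction and at least 0.5 log2 at the other, where counts were often too low to measure a fold. At stage 28, TRINITY_DN31339_c0_g1 (2172 bp) had 132 counts in the synarcual and 1 in the post-synarcual, a ratio of 129 with an interval of 22.8 to 5143. It had 0 counts in both stage 33 libraries, which allows up to 0.769 CPM in the synarcual and 0.986 CPM in the post-synarcual. TRINITY_DN20235_c0_g1 (946 bp) had 82 counts in the stage 28 synarcual and 0 in the post-synarcual, with 1 and 4 counts at stage 33. By the lower bound of its counting interval it was at least 21.3-fold higher in the synarcual at stage 28. Lower in the synarcual at stage 28 was TRINITY_DN28599_c0_g1 (2215 bp), with 1 against 233 counts and a 238-fold lower level (42.3 to 9440). TRINITY_DN60080_c0_g1 (861 bp) had 7 against 507 counts and a 74.0-fold lower level (35.6 to 185). At stage 33 their counts were 41 against 37 and 7 against 3 in the synarcual and post-synarcual. The ratios of post-synarcual over synarcual were then 1.16 (0.721 to 1.85) and 0.549 (0.0917 to 2.41). At these counts a region difference at stage 33 was not detectable for TRINITY_DN31339_c0_g1, TRINITY_DN20235_c0_g1 and TRINITY_DN60080_c0_g1, and is not shown to be absent.

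At stage 33, TRINITY_DN33288_c0_g1 (1934 bp) was 5.62-fold higher in the synarcual (2.88 to 12.2), with 72 against 10 counts, and had 16 and 17 counts at stage 28. TRINITY_DN32535_c0_g1 (4199 bp) differed at both stages in opposite directions, 4.16-fold higher at stage 33 (2.497 to 7.32) and 2.23-fold lower at stage 28 (1.57 to 3.21). Lower in the synarcual at stage 33 were TRINITY_DN42536_c1_g1 (2258 bp), by 9.79-fold (6.999 to 14.1), with 39 against 298 counts, and TRINITY_DN35449_c1_g1 (213 bp), by 5.68-fold (3.14 to 10.98), with 14 against 62 counts. Their stage 28 counts were 3 or fewer in each library, at which a region difference was not detectable.

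Region differences varied with the stage difference of a feature. Features with at least 200 counts in some library and a mean stage fold of at least 4 were divided into 530 late-high features, which were higher at stage 33, and 201 early-high features, which were higher at stage 28. These classes were defined after the data were examined. With TMM scaling the late-high features were lower in the synarcual, with a median log2 region fold of -0.62 at stage 28 and -0.52 at stage 33. The stage 33 median and the stage 33 numbers below rest on this scaling. Total counts moved the median of all features there to 0.45 log2. At stage 28, 161 of them were at least 2-fold lower in the synarcual and 14 higher. At stage 33, 202 were lower and 71 higher, and 99 were lower at both stages. For the 215 late-high features that were over 16-fold higher at stage 33, the median log2 region fold was -1.12 at stage 28 and -1.14 at stage 33. The early-high features had medians of 0.0298 and 0.0615, and the 4583 remaining features with the same minimum count had medians of 0.0659 and -0.0254. The late-high features took 3.57% of counts in the synarcual and 6.63% in the post-synarcual at stage 28, and 43.3% and 55.4% at stage 33. TRINITY_DN41535_c0_g1, named above, is among them.

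**Figure D3:**
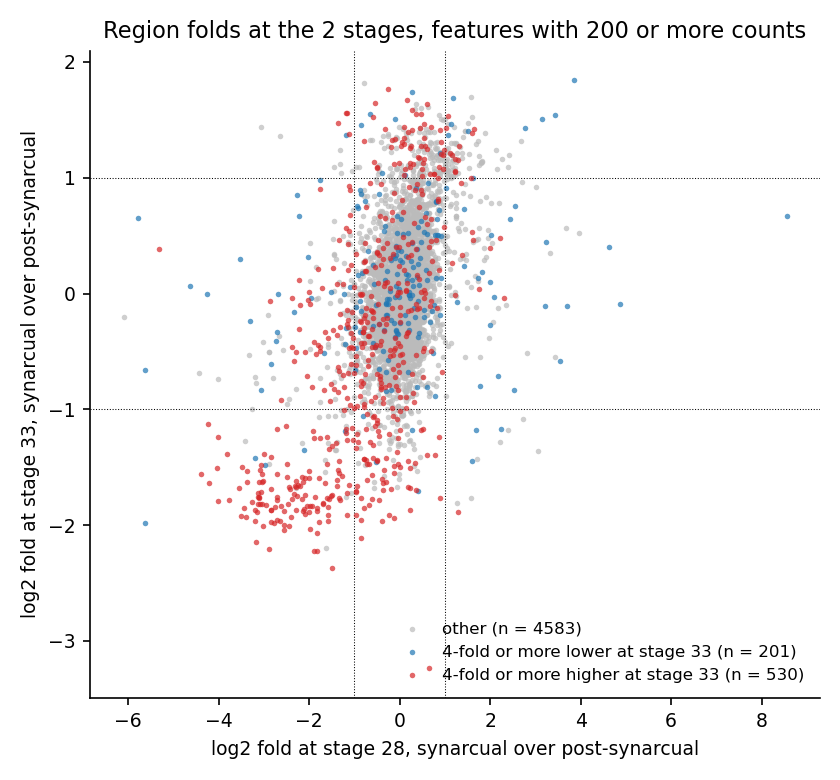
Log2 fold of the synarcual over the post-synarcual at stage 28 (x axis) and stage 33 (y axis) for each feature with at least 200 counts in some library, with dotted lines at 2-fold. The 530 late-high features (red) extend to the lower left, where 99 are at least 2-fold lower in the synarcual at both stages, while the 201 early-high features (blue) have medians of 0.0298 and 0.0615.

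The folds of the late-high features were distributed differently at the 2 stages. At stage 33, 125 of the 530 lay between -2 and -1.5 on the log2 scale, 64 between -1.5 and -1, 68 between -1 and -0.5, 89 between -0.5 and 0, 68 between 0 and 0.5, 32 between 0.5 and 1, and 60 between 1 and 1.5. At stage 28 the most filled window of the same width was that from -0.5 to 0, with 101 features, and 44 lay between -2 and -1.5. The region folds of the late-high features at the 2 stages correlated across features (Pearson r = 0.60, Spearman rho = 0.62), against 0.25 and 0.23 among the early-high features and 0.33 and 0.30 among the remaining features. Early-high features held 0.27% of counts in the stage 33 synarcual and 0.19% in the post-synarcual, so their stage 33 folds rest on few counts. How far this lowers their correlation was not tested.

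**Figure D4:**
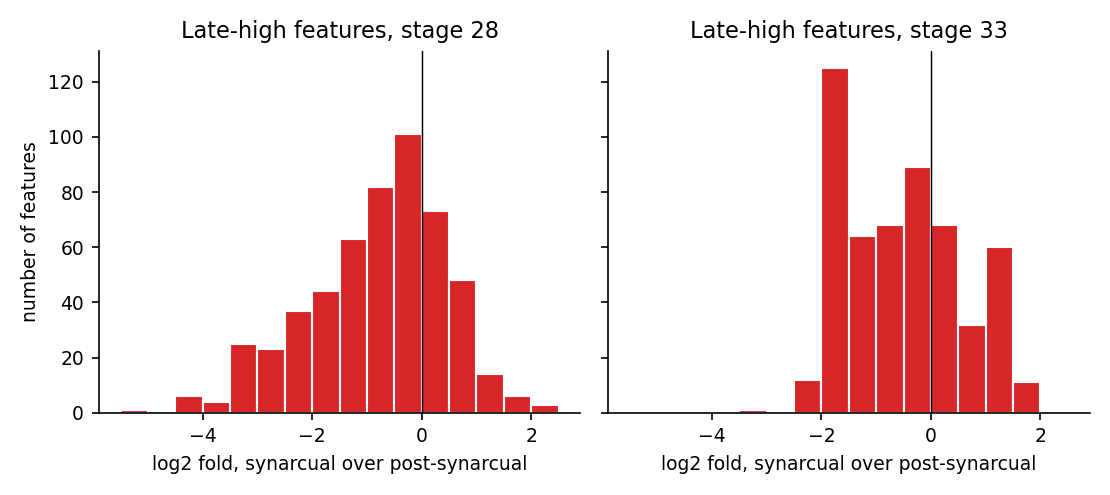
Number of late-high features (y axis) in windows of 0.5 of the log2 fold of the synarcual over the post-synarcual (x axis), at stage 28 on the left and stage 33 on the right. At stage 33 the fullest window holds 125 features between -2 and -1.5, and at stage 28 it holds 101 features between -0.5 and 0.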

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

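The tests in this part were chosen after the numbers they bear on were seen. The region difference had opposite directions at the 2 stages in 23 features that were at least 2-fold apart at both: 8 were higher in the synarcual at stage 28 and lower at stage 33, and 15 the reverse. The difference between the stages was not tested, since each group has 1 library. Of the named features, TRINITY_DN32535_c0_g1 is one of them, with a log2 region fold of -1.12 at stage 28 and 1.98 at stage 33, a difference of 3.10. Another, singled out after its values were seen, is TRINITY_DN30875_c0_g1, a feature of 9530 bp and the most abundant of the stage 28 synarcual. It had 61854 counts there against 25121 in the stage 28 post-synarcual, and 51062 against 139276 at stage 33.

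Counting error alone is argued against as the source of these 23 features, since simulations of it gave 0 on average. Adding the fitted spread, as 1 value for all features, gave 3.95. In the test's check, a spread drawn per feature raised unchanged features that the rule of size called at both stages from 2 to 47. Opposite directions were not counted there, so spread between libraries stays open. The number of features with opposite directions is not above what the calls of each stage would give if they were independent, 27.6 features. Whether the stage or the animals sampled at each stage set these directions stays open, because the design gives 1 set of animals per stage.

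The stage difference had opposite directions in the 2 regions in 9 features, of which 6 were at least 2-fold higher at stage 33 in the synarcual and lower in the post-synarcual, and 3 the reverse. This was not tested either.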

How the results depend on the processing

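The sums by component, and all settings for the region differences shared by both stages, were chosen after seeing the data. The region test over both stages, which called 0 features with edgeR, called 57 with DESeq2 size factors, 258 with total-count scaling, 1110 without a low-count filter, 376 with a filter of 50 counts, 222 with DESeq2's Wald test (3697 adjusted p values were NA), 73 at an adjusted p of 0.1 and 197 with counts summed by component. Without the stage as the replicate block it called 0. It called 7 higher and 50 lower in the synarcual with DESeq2 size factors, and 105 and 153 with total-count scaling. With a filter of 50 it called 163 and 213, without a filter 553 and 557, and with sums by component 60 and 137. Its lowest adjusted p over the settings ranged from 2.90e-48 (no filter) to 0.99999 (no block). The cause was not tested. The differences in size at stages 28 and 33 between regions, and between stages in the synarcual and post-synarcual, numbered 378, 503, 1742 and 1493 with a minimum count of 200, and 291, 33, 1421 and 1248 at 4-fold, which are fewer by construction. A minimum count of 20 gave 1503 at stage 28. Total-count scaling gave 1692 region differences at stage 33, and 5699 and 7440 stage differences. TPM gave 1633 at stage 33, and 6198 stage differences in the post-synarcual. These scalings moved the median of all features, to as low as -1.28 log2 in the post-synarcual stage comparison under total counts. Stage differences shared by both regions, 2267, became 4587 with total counts, 1016 at a minimum of 200 and 824 at 4-fold. Region differences shared by both stages, 254, became 93 and 5 under the latter settings. The region contrast, 798, became 426 and 129, the stage contrast, 3599, became 6766 with total counts, 1782 and 1341, and the interaction contrast, 244, became 420 with total counts, 156 with a prior count of 8, 111 and 16. The correlation of region folds was 0.39 with a filter of 50 and 0.19 with none, and that of stage folds 0.76 with none. Of 104 alternative values of the comparisons, 66 stayed within 1.5 times the main count or within 0.05 of the main correlation. The 66 include a setting that used the deposited series table, whose counts are the same, so its values could not move. The limit compares totals only. In TPM the stage contrast stayed within it, while its upward share went from 53.9% to 20.6%. No named feature turned direction under any setting run. The 4 planned settings for the gene lists were not run, because the lists could not be matched. Leaving out 1 library leaves no residual degree of freedom in the region test, so the folds of each stage alone take its place. Depth limits the features with few counts: the median count per feature was 30 in both stage 28 libraries, 23 in the stage 33 synarcual and 17 in the stage 33 post-synarcual.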

Other observations

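The tests of transcript length, effective depth and the most abundant features were set out before their results were seen, and the other tests of this part after. Some features had counts at 1 stage alone, which does not show that they were absent at the other. In both stage 33 libraries, 12 features had at least 50 counts and none at stage 28; their counts ranged from 52 to 2226 and together made up 0.108% of the stage 33 counts. The reverse held for 2 features, with counts from 52 to 62. Features with at least 50 counts in 1 library and at most 3 in the rest numbered 10 in the stage 28 synarcual, 3 in the stage 28 post-synarcual and 0 in each stage 33 library. The most abundant of them, TRINITY_DN32019_c0_g1, singled out after its values were seen, had 939 counts in the stage 28 synarcual and 1 in all other libraries together. It had the largest upward region fold of all features compared at stage 28, though the naming rule did not select it. The 840 pairs of features from the same assembly component had related folds, with a correlation of 0.60 for the region fold and 0.78 for the stage fold, against at most 0.0840 in 100 shuffles of the pairs.

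The late-high features, picked anew under each of the other scalings, prior counts and sums by component, lay lower in the synarcual at both stages. Their medians ran from -0.94 to -0.56 at stage 28 and from -0.55 to -0.29 at stage 33. For the same 530 features the distance below 0 at stage 33 rests on the scaling. Total counts moved the median of all features there to 0.45 log2. Counting error is argued against, since the medians of -0.62 and -0.52 lay below the lowest medians simulated from it, -0.0173 and -0.00301. For the gap to the remaining features, a library-wide scaling error is argued against, since every feature of a library shares its factor. The late-high median differed from theirs by -0.69 and -0.50 log2. Transcript length is argued against too, as the lowest median of 1000 length-matched random sets was 0.0456 at stage 28 and -0.11 at stage 33. A tissue present in different shares stays open: 25.5% of the features chosen by their stage 28 fold lay within 0.25 log2 of their median at stage 33, and 11.9% in the reverse choice, far below the 97.9% and 62.1% that counting error alone allows, but the spread between libraries that this would be held against is not measured with 1 library per group. Later timing in the synarcual that shifts early-high and late-high features by equal amounts stays open at both stages. The early-high medians of 0.0298 and 0.0615 fell short of the size needed by 0.59 at stage 28 and 0.46 at stage 33. The yardstick set for this was their interquartile range divided by 2 (0.61 and 0.39). The shortfall exceeded it at stage 33, which is the result predicted if such timing is not the cause, and did not at stage 28. The yardstick is a spread across features and not an error of the median, so it is not taken to decide stage 33. The shortfall also depends on the scaling. Early-high features held only 0.27% of stage 33 counts in the synarcual and 0.19% in the post-synarcual. A shift of co-varying features in 1 library would bear on 1 stage only, as the stages share no library, and separate shifts at each stage were not tested. A spread that differs between libraries could tie the region fold to the stage fold, and was not tested either.

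Region differences of 4-fold or more numbered 291 at stage 28 and 33 at stage 33, which was not tested because each group has 1 library. At 2-fold the order was the reverse, with 987 features or 9.33% of those compared at stage 28 and 1058 or 11.8% at stage 33. The lower effective depth at stage 33 is argued against, since stage 28 libraries thinned to it still gave 220.8 features beyond 4-fold on average, as is the concentration of counts in few features, since without the 185 features among the 100 most abundant of any library the numbers were 265 and 34. Under other scalings and prior counts the 4-fold numbers ranged from 218 to 312 at stage 28 and from 21 to 59 at stage 33. Large regional differences that narrow between the stages, tissue of one region carried into the other at stage 33, and differences between the animals of each stage may each be the source, and no test here separates them.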
